A study of Arabidopsis thaliana with 3 samples.

How the data were processed

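Expression was measured on 2-colour Agilent oligonucleotide arrays in whole Arabidopsis thaliana seedlings, aged 3 days, of the mutant tdt-1 and of wild type. Per the labels, the seedlings grew on MS agar plates in constant light at 22 °C, and total RNA was amplified linearly and labelled with Cy3 or Cy5. Each of 3 arrays held tdt-1 RNA in 1 channel and wild-type RNA in the other, so every array pairs the genotypes. Per the labels, the 3 arrays are biological replicates, with tdt-1 in Cy5 in replicates 1 and 2 and in Cy3 in replicate 3.

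The scanner files hold spot intensities on a linear scale, deposited as the mean pixel value and the median local background of each channel, before correction. Per the file headers, the intensities came from Agilent Feature Extraction, version 8.5.1.1 for replicates 1 and 2 and version 9.1.3.1 for replicate 3. The headers also show that replicates 1 and 2 shared an array layout of 206 rows and 215 columns, a scan day and a resolution of 10 micron. Replicate 3 was on a later layout of 532 rows and 85 columns, scanned on another day at 5 micron. All 3 arrays carried the same 37478 noncontrol probes on 37685 spots. The files also give a log10 ratio of Cy5 over Cy3, which, per the file headers, the software computed after spatial detrending and its own dye normalization, and 0 or 1 flags for spots well above background, saturated or non-uniform. The threshold multiplier for the flag of a spot well above background was 2.6 in the earlier version and 13 in the later one, per the file headers. The deposited series table holds log2 ratios. Set against the scanner log ratios of the same arrays, its columns had slope 1 and r = 1 once the ratio of replicate 3 was turned, so its values are log2 of tdt-1 over wild type, with a median of 0 on each array, and nothing about its scale or direction stayed open.

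From the intensities, background was corrected with limma's normexp (offset 50), log ratios were normalized by loess within each array with control spots at weight 0, and the sign was turned on replicate 3. Control spots and non-uniform outlier spots (16, 11 and 81 on replicates 1, 2 and 3) were then left out, and spots of 1 probe were averaged. A probe was tested where tdt-1 or wild type was well above background on all 3 arrays. Of several probes of a locus, the brightest stood for the gene. Of 37478 probes, 26236 carried a locus code, for 25665 loci, of which 25449 matched the reference table (assembly TAIR10.1, used for names only) and 216 did not. In all, 20484 loci were tested, 424 of them with more than 1 tested probe. Among the changed loci, 60 had more than 1 tested probe, and in 6 another probe had the opposite sign.

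Each gene's log2 ratio was tested against 0 with limma's lmFit and eBayes over the 3 arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05. No dye term was fitted in the main test, since it leaves 1 residual degree of freedom, and a separate test of that term is reported. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, where at least 4 members were tested. Lists were matched by locus code. They comprised 24 lists of named loci and 4 lists made by a rule: loci described as 40S or 60S ribosomal proteins, plastid and mitochondrial genome loci, and loci whose description, name or type mentions transposition. Called genes along the chromosomes were compared with 10000 random draws in windows of 100 neighbouring tested genes. The lists, the tests and the alternatives were fixed before the data were examined, except where the text says otherwise. The alternatives covered background correction, normalization, filters, probe choice, the dye term, array weights, the variance model and leaving out each array. Replicates 1 and 2 averaged as 1 replicate was added after seeing the data.

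Genes are named by a rule fixed in advance: loci with the symbol or synonym TDT, the 15 highest and the 15 lowest ratios among genes past the test with the same sign on all arrays, the 4 members with the smallest p of each list past camera or with at least 3 members past the test, otherwise the 1 with the smallest p, the 3 smallest p of the dye term, and the 4 smallest p in the densest window. The values of 1 gene that the rule names are not reported. Names follow the reference table where a list's symbol was not in it. Levels of a genotype below the flag on all arrays would be given as bounds, but none of the genes named by the rule needed one.

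The number of arrays limits the precision. The share of noncontrol spots well above background lay between 65.2% and 69.4% in tdt-1 and between 69.4% and 79.7% in wild type. On the 23 probes spotted 10 times, the median SD between spots was 0.080, 0.066 and 0.025 on replicates 1, 2 and 3. Replicates 1 and 2 were kept as separate replicates because the labels give them as such. The arrays hold no repeat hybridization of 1 RNA that would test it, so the counts are also given with both averaged. The procedure was tested on simulated data built from the real levels and spreads of the 20484 genes. With 200 planted changes, 2.99% of those of log2 size 0.5, 82.1% of size 1 and 97.0% of size 2 were recovered, with 8 false calls. With 2000 planted changes the shares were 47.4%, 96.0% and 99.9%, with 86 false calls. Errors were drawn independently for each simulated array, while the real ratios of replicates 1 and 2 lay far closer to each other than to those of replicate 3. These shares and false calls therefore need not hold for the real arrays. Computations used R 4.3.3, limma 3.58.1 and version 1.17.8 of data.table.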

Results

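The comparison was made on 3 arrays, each holding RNA of tdt-1 seedlings against RNA of wild-type seedlings of the same age, 3 days. All values are log2 ratios of tdt-1 over wild type, given as the mean ± SD over the 3 arrays. The question was which transcripts differ in level between the mutant and wild type in whole seedlings. The median spot signal was 91.5, 97.5 and 269.9 for tdt-1 and 185.5, 172.2 and 402.4 for wild type on replicates 1, 2 and 3.

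The labels do not name the gene affected in tdt-1. The reference table gives TDT and TRIDENT as synonyms of DCP2 (AT5G13570), the catalytic subunit of the mRNA decapping enzyme, and work on trident mutants places their lesions in that gene. The DCP2 probe was lower in tdt-1 on all 3 arrays, at −0.44, −0.46 and −0.96, with a mean of −0.62 ± 0.29 that did not pass the test (limma adjusted p = 0.0629). A second locus, TDT (AT5G47560), which encodes the tonoplast dicarboxylate transporter, stood at −0.19 ± 0.47 (adjusted p = 0.545), with ratios of 0.10, 0.06 and −0.74. The lesion's place relative to the probes is not given in the sources used here, so neither value checks the genotype labels.

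In tdt-1 seedlings, transcripts of small heat shock proteins stood highest above wild type, and transcripts for iron uptake and for methionine chain elongation stood lowest. ATHSP22.0, a chaperone of the endoplasmic reticulum, was 32.1-fold higher (5.0 ± 0.46), and the chloroplast chaperone HSP21 was 20.8-fold higher (4.38 ± 0.32). FRO2, the root ferric chelate reductase, was 19.2-fold lower (−4.27 ± 0.26), and the iron transporter IRT1 was 15.6-fold lower (−3.96 ± 0.59). BCAT4, an aminotransferase that starts the chain elongation of methionine for aliphatic glucosinolates, was 14.8-fold lower (−3.89 ± 0.35). In all, 1508 of 20484 tested genes were higher in tdt-1 and 1222 were lower (limma, adjusted p under 0.05), all 2730 with the same sign on all 3 arrays, and 466 and 379 of them changed at least 2-fold. Loess centred each array, with median ratios of 0.04, 0.03 and −0.007 on replicates 1, 2 and 3. The counts are therefore relative to the bulk of transcripts, and a shift shared by most of them would not show. The smallest adjusted p was 0.0126, and 7181 genes had an unadjusted p under 0.05. With median centring in place of loess only 1 gene passed, and the counts moved with each array left out: 115 higher and 82 lower without replicate 1, 66 and 45 without replicate 2, and 7002 and 5463 without replicate 3. With replicates 1 and 2 averaged, an alternative added after seeing the data, 24 genes were higher and 19 lower. A dye term gave 6941 and 6260, and array weights 8170 and 6710. All 2730 genes kept their sign in each of these alternatives. Apart from median centring, however, these alternatives only leave out, average or reweight the same ratios. Those ratios shared a sign on all 3 arrays for every called gene, so it could not turn there. The larger counts with a dye term or without replicate 3 rest on the spread between replicates 1 and 2 alone. Those with array weights rest mainly on it, since replicate 3 had a weight of 0.11 against 1.27 and 7.40. As they leave out the spread toward replicate 3, they are no measure of further changed genes.

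The 15 highest ratios included, besides ATHSP22.0 and HSP21, the small heat shock proteins AT1G52560 (4.21 ± 0.41), HSP18.2 (3.63 ± 0.47), AT1G53540 (3.42 ± 0.45) and HSP23.6-MITO of the mitochondria (3.23 ± 0.26) and AT1G07400 (3.36 ± 0.77). AT2G29500, described as a further class I small heat shock protein, reached 3.21 ± 0.79. The other high ratios included CORI3, a coronatine-responsive aminotransferase (3.71 ± 0.57), the plastid protease FTSH6 (3.69 ± 1.0), RD20, a calcium-binding protein induced by abscisic acid (3.42 ± 0.78), LEA7, a late embryogenesis abundant protein (3.3 ± 0.57), the beta-amylase BAM5 (3.28 ± 0.80), the lipid transfer family protein AT2G37870 (3.25 ± 0.43) and AT5G07330, of no described function (3.12 ± 0.23).

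Among the 15 lowest ratios, BCAT4 was joined by further enzymes of methionine chain elongation: MAM1 (−3.15 ± 0.56), IMS2 (−3.07 ± 0.44) and IMD1 (−2.90 ± 0.40). ZIP8, described as a metal transporter and well above background in tdt-1 on 2 of 3 arrays, stood at −2.96 ± 0.21. GASA6, a gibberellin-regulated peptide, reached −3.28 ± 1.29, with −4.74 on replicate 3 against −2.33 and −2.75 on replicates 1 and 2. The others were AT3G16670 (−3.59 ± 0.26), AT2G28780 (−3.15 ± 1.06), the glycine-rich protein AT4G29030 (−2.82 ± 0.39), MLP34 (−2.76 ± 0.09), the amino acid permease AAP2 (−2.61 ± 0.34), DJ1F (−2.52 ± 0.15) and the ovate family protein OFP16 (−2.48 ± 0.68).

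**Figure D1:**
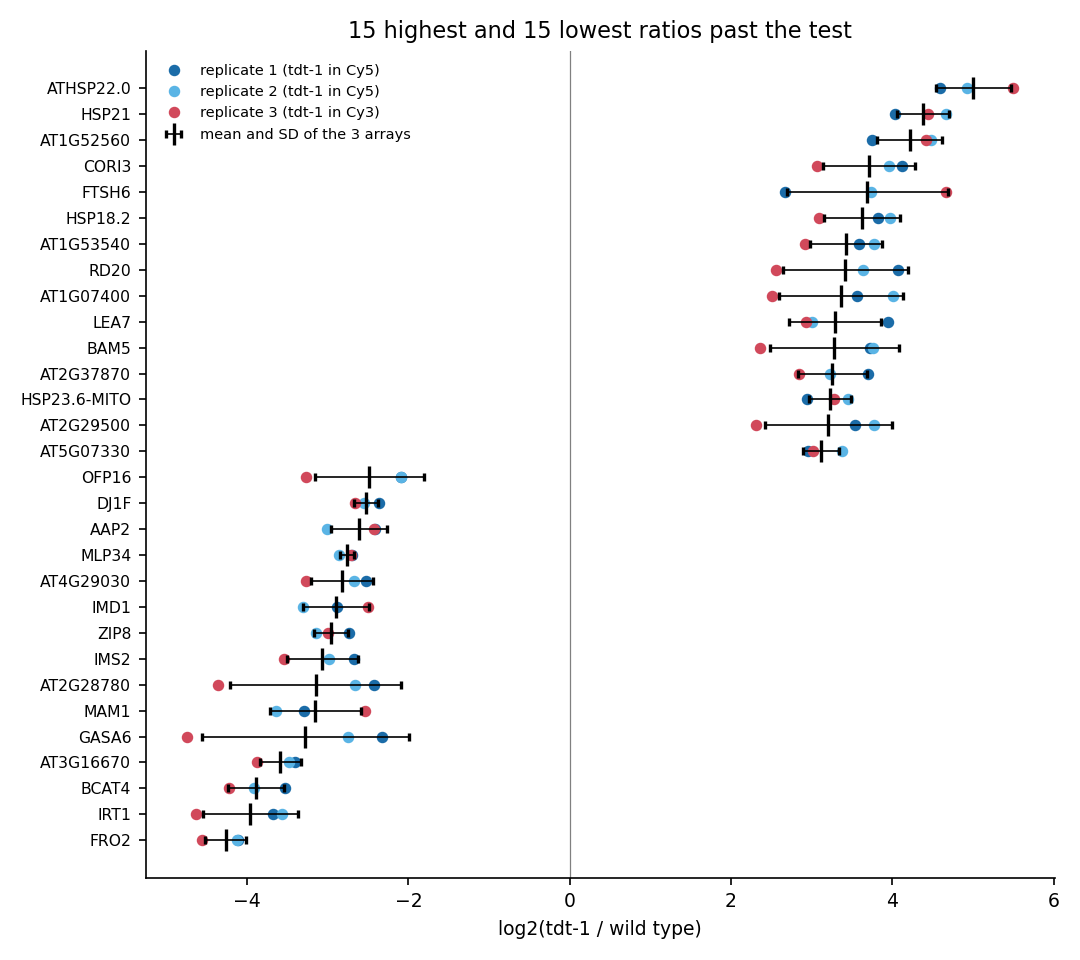
Log2 ratios of tdt-1 over wild type (x axis) for the 15 highest and 15 lowest genes past the test, with a point per array and a bar for the mean and SD of the 3 arrays. The ratios run from −4.27 for FRO2 to 5.0 for ATHSP22.0, and the 3 arrays of each gene lie on the same side of 0.

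Of the heat shock response list, 20 of 22 tested members rose and 2 did not pass, and 20 rose when adjusted over the list alone, where 1 fell. Beside the small heat shock proteins, DREB2A, a transcription factor of the heat and drought responses, rose by 1.92 ± 0.12. The list median was 2.38, at 2.31, 2.78 and 2.41 on replicates 1, 2 and 3, and camera gave an adjusted p of 3.85e-14. That call was lost with an estimated correlation (adjusted p = 0.626 with an estimated correlation), while fry gave an adjusted p of 0.0204.

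Of 23 tested members of the abscisic acid, cold and water stress response list 14 rose, none fell and 9 did not pass, and 19 rose when adjusted over the list alone. The dehydrin gene RAB18 rose by 2.61 ± 0.56, the cold-regulated COR15A by 2.85 ± 0.77, RD29B by 1.79 ± 0.54 and ABI2, a phosphatase of abscisic acid signalling, by 1.84 ± 0.38. The list median was 1.54 and 1.33 on replicates 1 and 2 and 0.53 on replicate 3, with a camera adjusted p of 1.43e-08 (adjusted p = 0.740 with an estimated correlation). Fry did not pass for this list (adjusted p = 0.0970), and the median over all arrays of 1.19 became 0.78 without replicate 1.

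Seed and early seedling genes were higher in part. Of 19 tested members of the seed storage and maturation list 3 rose and 16 did not pass, with the same 3 counted when adjusted over the list alone: EM1 (1.45 ± 0.13), M17 (1.51 ± 0.35), both late embryogenesis abundant proteins, and ABI5, a transcription factor of seed maturation (0.69 ± 0.20). The storage protein gene SESA5, well above background in wild type on 2 of 3 arrays, stood at 0.88 ± 0.57 (adjusted p = 0.0848). The list's median was 0.66, with a camera adjusted p of 0.00922 (adjusted p = 0.626 with an estimated correlation) and a fry adjusted p of 0.0484. Median centring ended its camera call (adjusted p = 0.0773), and array weights lowered its median to 0.39. Of 18 members of the seed lipid mobilisation and glyoxylate cycle list 6 rose, none fell and 12 did not pass, again with 6 when adjusted over the list alone. They included MLS, the malate synthase of the glyoxylate cycle (2.04 ± 0.36), CSY3, a peroxisomal citrate synthase (1.45 ± 0.19), and KAT2 and ACX1 of fatty acid beta-oxidation (1.17 ± 0.06 and 0.96 ± 0.11). Its median was 0.41 (0.67 with median centring and 0.22 with array weights), camera gave an adjusted p of 0.00107 (adjusted p = 0.626 with an estimated correlation) and fry 0.0484.

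Of 20 tested genes for oxidative stress and detoxification 6 rose, 1 fell and 13 did not pass, and 7 rose and 1 fell when adjusted over the list alone. APX2, a cytosolic ascorbate peroxidase, rose by 2.58 ± 0.39, AT2G21640 by 1.92 ± 0.39, the glutathione transferase GSTF6 by 1.73 ± 0.21 and the zinc finger protein ZAT10 by 0.99 ± 0.09. The median was 0.28, or 0.45 without replicate 1, 0.48 without replicate 2 or with a dye term and 0.52 with median centring, with a camera adjusted p of 0.00952 (adjusted p = 0.626 with an estimated correlation) and a fry adjusted p of 0.00906. Of 26 genes for the cell cycle and DNA replication 3 rose by small amounts and 23 did not pass, and 4 rose when adjusted over the list alone: MCM6 (0.50 ± 0.04) and MCM7 (0.58 ± 0.14) of the replicative helicase and the cyclin CYCB2;1 (0.44 ± 0.06) passed over all genes, and PCNA2 stood at 0.57 ± 0.20 (adjusted p = 0.0504). Camera gave an adjusted p of 0.0412 (adjusted p = 0.740 with an estimated correlation) at a median of 0.13. That call was lost without replicate 1 (0.0862) or without replicate 2 (0.211), and with the scanner's own log ratio (0.0631), median centring (0.116), a dye term (0.0860) or replicates 1 and 2 averaged (0.136).

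Genes for photosynthetic light reactions and the Rubisco small subunit had a list median below 0 on every array, but by unequal amounts. It was −0.27 and −0.36 on replicates 1 and 2 and −2.43 on replicate 3. Of 38 members 2 fell and 36 did not pass, and none passed when adjusted over the list alone. The 2 were LHCB1.3, a light-harvesting protein of photosystem II (−0.75 ± 0.30), and RBCS1B, a Rubisco small subunit (−0.99 ± 0.44 as read). The RBCS1B spot was saturated in wild type on 2 of 3 arrays, so that its ratio there bounds the size of the fall from below, and 15 of the 38 members had a saturated spot on replicate 1 or 2. PSAN and LHCA2 of photosystem I stood at −1.53 ± 0.78 (adjusted p = 0.0526) and −1.38 ± 0.75 (adjusted p = 0.0599). The list median of −1.05 became −0.31 without replicate 3 and −0.38 with array weights. Camera gave an adjusted p of 6.10e-08 (adjusted p = 0.740 with an estimated correlation), and fry 0.316.

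Genes of chlorophyll biosynthesis had list medians of −0.64, −0.42 and −0.81 on replicates 1, 2 and 3. Of 18 members 9 fell, none rose and 9 did not pass, and 14 fell and 2 rose when adjusted over the list alone. GSA2, of the synthesis of 5-aminolevulinate, fell by 1.16 ± 0.21, CHLD, a subunit of magnesium chelatase, by 0.98 ± 0.23, CHLM by 1.32 ± 0.39 and CHLG, the chlorophyll synthase, by 1.05 ± 0.27. Camera gave an adjusted p of 7.63e-05 (adjusted p = 0.626 with an estimated correlation) at a median of −0.65 (−0.36 with median centring), and fry 0.0616.

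The auxin response list had medians of −0.27, −0.13 and −0.92 on replicates 1, 2 and 3. Of 24 members 6 fell, none rose and 18 did not pass, and 9 fell when adjusted over the list alone. IAA19 and IAA1, repressors induced by auxin, fell by 1.04 ± 0.20 and 0.72 ± 0.08, and the auxin-conjugating enzyme gene GH3.3 fell by 1.38 ± 0.37. The median was −0.50, or −0.22 without replicate 3, −0.17 with array weights and −0.32 with median centring, with a camera adjusted p of 6.66e-06 (adjusted p = 0.740 with an estimated correlation) and a fry adjusted p of 0.156.

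Of 18 tested members of the iron deficiency response list 6 fell, none rose and 12 did not pass, with 6 again when adjusted over the list alone. With FRO2 and IRT1, FRU (also called FIT), the transcription factor that drives iron uptake, fell by 2.17 ± 0.10 and the nicotianamine synthase gene NAS1 by 1.5 ± 0.08. Others were lower on replicate 3 alone: BHLH38, a partner of FRU, stood at 0.70, 0.98 and −5.68 on replicates 1, 2 and 3, and AT1G47400 at 0.70, 1.02 and −6.35. The list median was −0.88, −0.42 and −3.45 on replicates 1, 2 and 3, and −1.52 over all arrays, −0.62 without replicate 3 and −0.49 with array weights. Camera gave an adjusted p of 9.18e-06 (adjusted p = 0.692 with an estimated correlation), and fry 0.0624.

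**Figure D2:**
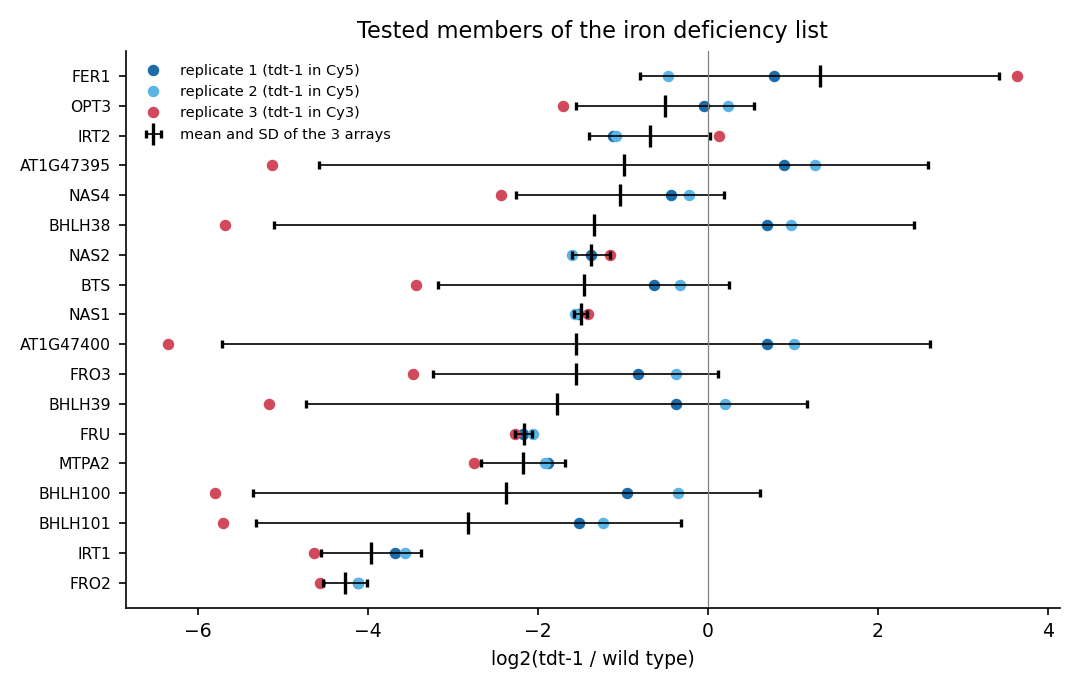
Log2 ratios of tdt-1 over wild type (x axis) for the 18 tested members of the iron deficiency list, with a point per array and a bar for the mean and SD of the 3 arrays. FRO2, IRT1, FRU, MTPA2, NAS1 and NAS2 have like ratios on the 3 arrays, while BHLH38 and AT1G47400 lie at 0.70 to 1.02 on replicates 1 and 2 and at −5.68 and −6.35 on replicate 3.

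Of 14 genes of the phosphate starvation response 2 fell and 12 did not pass, over all genes and when adjusted over the list alone. They were the phosphate transporter gene PHT1;1 (−1.32 ± 0.31) and PHO1;H1 (−1.45 ± 0.64). PHT1;4 stood at −0.96 ± 0.77 (adjusted p = 0.118), and PHT1;5, well above background in wild type on 1 of 3 arrays, at 0.49 ± 0.22 (adjusted p = 0.0697). The median was −0.86, with a camera adjusted p of 0.0460 (adjusted p = 0.884 with an estimated correlation) and a fry adjusted p of 0.471. It was −0.18, 0.23 and −1.92 on replicates 1, 2 and 3, and the call was lost without replicate 3, where the median was 0.01, with array weights (median 0.17, adjusted p = 0.767) and with no background correction (adjusted p = 0.0521).

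Several lists that did not pass camera held changed members in opposite directions. Of 21 circadian clock genes 5 fell and 1 rose, or 5 and 4 when adjusted over the list alone. Those that fell included RVE1 at −1.99 ± 0.12, LNK2 at −2.28 ± 0.40, CCA1 at −1.26 ± 0.34 and RVE8 at −0.82 ± 0.13 (camera adjusted p = 0.929). The clock list's median of 0.16 lay above 0 while its mean of −0.15 and camera's direction lay below. Of 23 flavonoid and anthocyanin genes 7 rose and 1 fell (7 and 3 over the list alone), the former including LDOX (1.32 ± 0.25), AT5MAT (1.24 ± 0.10), AT4G14090 (1.18 ± 0.04) and GSTF12 (0.91 ± 0.09), at a camera adjusted p of 0.509. The flavonoid list median of 0.003 became −0.27 without replicate 3. Of 24 light signalling genes 2 rose and 3 fell (4 and 5 over the list alone, camera adjusted p = 0.356): PIL1 (1.23 ± 0.02) and PIF3 (1.01 ± 0.20), both bHLH transcription factors, rose, and COL2 (−1.64 ± 0.20) and COL1 (−0.61 ± 0.03) fell. PIL1 was well above background in wild type on 2 of 3 arrays.

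The other hormone lists did not pass camera. Of 18 jasmonate genes 3 rose and 2 fell, with the same counts over the list alone (camera adjusted p = 0.524), among them the transcription factor MYC2 (1.04 ± 0.21) and LOX3 (0.58 ± 0.11) upward and the repressors JAZ6 (−0.85 ± 0.20) and JAZ9 (−0.99 ± 0.29) downward. Of 14 gibberellin genes 1 rose, GID1B (0.91 ± 0.30), and 2 fell, GA3OX1 (−0.76 ± 0.15) and RGA (−0.61 ± 0.11), with 1 and 3 over the list alone (camera adjusted p = 0.521). GA20OX1 stood at −0.46 ± 0.19 (adjusted p = 0.0699). Of 19 salicylate and defence genes 2 rose, 1 over the list alone, with WRKY18 at 1.44 ± 0.19 (camera adjusted p = 0.0837). Without replicate 3 camera called the salicylate list (adjusted p = 0.0113) and the jasmonate list (adjusted p = 0.0496) higher, and with array weights the salicylate list (adjusted p = 0.0159), all at the preset correlation. Over all arrays the salicylate list had an adjusted p = 0.884 and the jasmonate list an adjusted p = 0.943 with an estimated correlation. HCHIB, a basic chitinase at 1.44 ± 0.27, was the member that rose of 14 ethylene genes, also over the list alone (camera adjusted p = 0.451, fry adjusted p = 0.0484). Of 12 cytokinin genes 1 rose, ARR8 (0.86 ± 0.25), and 1 fell, or 2 and 1 over the list alone (camera adjusted p = 0.960), with the list's median and mean above 0 and camera's direction below. None of 11 brassinosteroid genes passed, over all genes or the list alone (camera adjusted p = 0.929), and BZR1 stood at 0.42 ± 0.05 (adjusted p = 0.0508).

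Of 12 genes for carbon starvation and sugar response 1 rose, DRM1 (1.59 ± 0.64), and 2 fell, the glucose transporter gene STP1 (−1.44 ± 0.09) and DIN10 (−1.29 ± 0.30), or 6 and 3 over the list alone (camera adjusted p = 0.929, with fry's direction below 0 and the median above). GPT2 stood at 1.80 ± 1.04 (adjusted p = 0.0640). Of 20 cell wall genes 1 rose and 1 fell, with the same counts over the list alone, and the expansin gene EXPA8 fell by 2.3 ± 0.64 (camera adjusted p = 0.715). BRCA1 (0.55 ± 0.15) was the member that rose of 6 DNA damage genes, also over the list alone (camera adjusted p = 0.381). None of 13 root hair markers passed, over all genes or the list alone. The member with the smallest p, XUT1, stood at −0.69 ± 0.47 (adjusted p = 0.0989), the list's median was 0.03 while its mean of −0.06 and camera's direction were below 0 (camera adjusted p = 0.509), and without replicate 3 camera at the preset correlation called the list lower (median −0.27, adjusted p = 0.0113). Over all arrays the root hair list had an adjusted p = 0.943 with an estimated correlation. Of 223 cytosolic ribosomal protein genes 11 rose, none over the list alone, including RPL34 (0.68 ± 0.06), AT5G59240 (0.89 ± 0.23), AT2G19740 (0.63 ± 0.09) and RS27A (0.69 ± 0.16), at a camera adjusted p of 0.0837 and a median of −0.12 on replicate 1 and 0.45 on replicate 3. Camera called that list higher without replicate 1 (adjusted p = 9.59e-05) or replicate 2 (0.00520), with the scanner log ratio (0.0332), median centring (2.24e-07), a dye term (9.63e-05), replicates 1 and 2 averaged (0.000678) or no filter on dim probes (0.0420), and lower without replicate 3 (0.0300), all at the preset correlation. Over all arrays the ribosomal list had an adjusted p = 0.943 with an estimated correlation.

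Of 13 tested loci described with a transposition term 3 rose, also over the list alone (camera adjusted p = 0.314): AT1G47610, a WD-40 repeat protein by its description (1.39 ± 0.45), Sadhu4-2 (0.52 ± 0.07), and AT4G11200 (0.44 ± 0.07), which was well above background in wild type on 1 of 3 arrays. AT5G50120, a further WD-40 repeat protein, stood at −0.82 ± 0.49 (adjusted p = 0.0778). The 1 plastid genome locus tested, ATCG01000, fell by 1.16 ± 0.09, and none of the 3 mitochondrial genome loci passed over all genes, with ATMG00580 at −0.55 ± 0.26 (adjusted p = 0.0675) and 1 lower over the list alone. Camera was not run on these organelle lists.

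**Figure D3:**
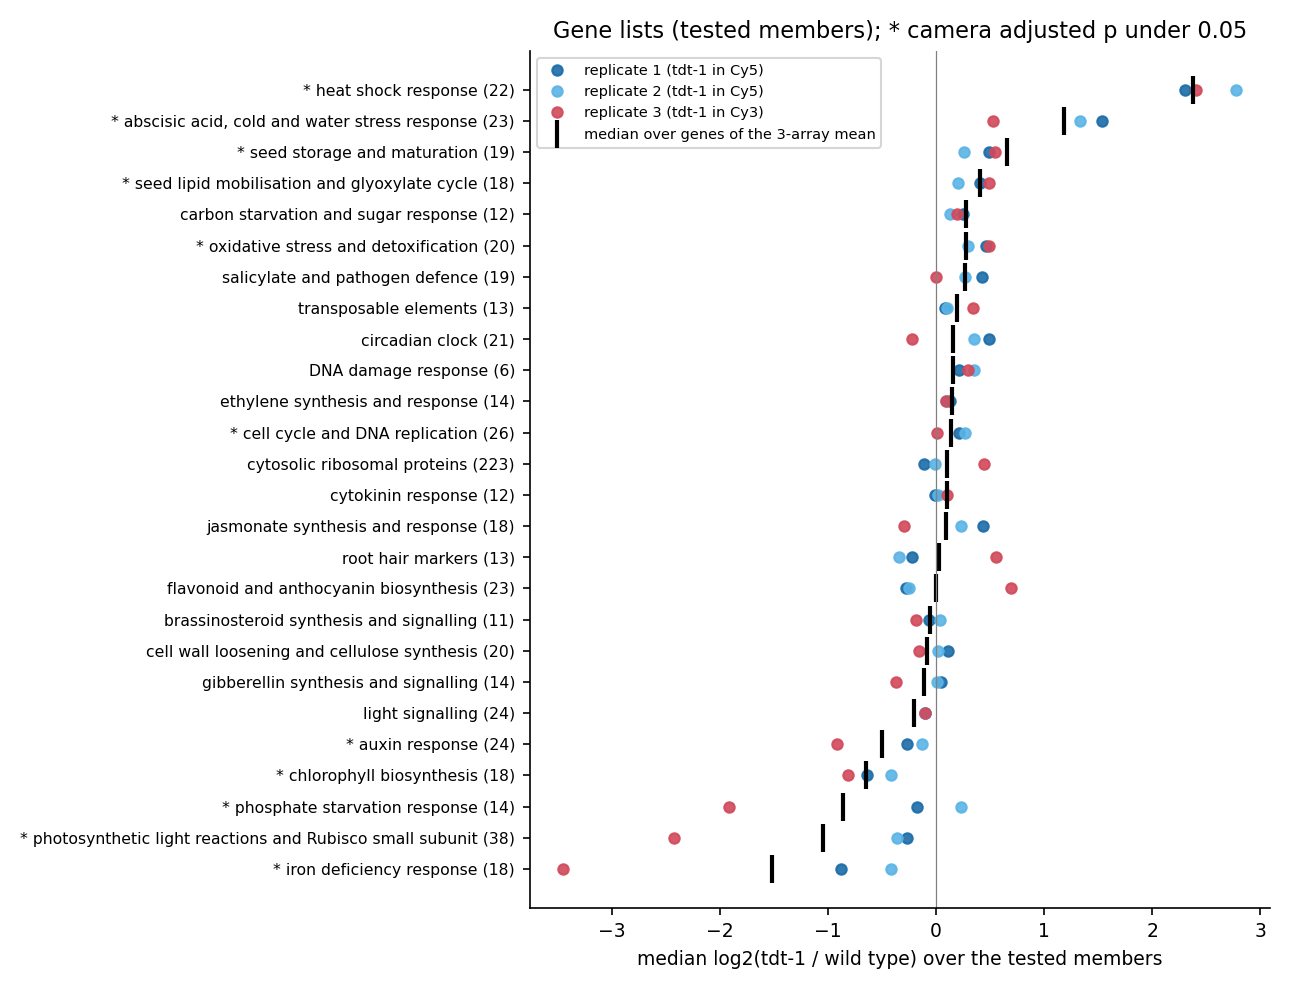
Median log2 ratio of tdt-1 over wild type (x axis) over the tested members of each gene list, with a point per array and a bar for the median of the 3-array means. Heat shock genes lie at 2.31, 2.78 and 2.41 on the 3 arrays, while the photosynthesis, phosphate and iron lists lie farther below 0 on replicate 3 than on replicates 1 and 2.

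The arrays differed in how closely their ratios followed each other. Across the 20484 genes, which are not independent replicates, replicates 1 and 2 correlated at Pearson r = 0.940 (Spearman rho = 0.918), replicates 1 and 3 at 0.527 (0.447) and replicates 2 and 3 at 0.573 (0.50). The SD of the ratios was 0.523, 0.516 and 0.708 on replicates 1, 2 and 3. Replicate 3 was the dye-swapped array and also the one with its own layout, scan day and software version, so these cannot be told apart, and no within-day value other than that of replicates 1 and 2 exists.

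**Figure D4:**
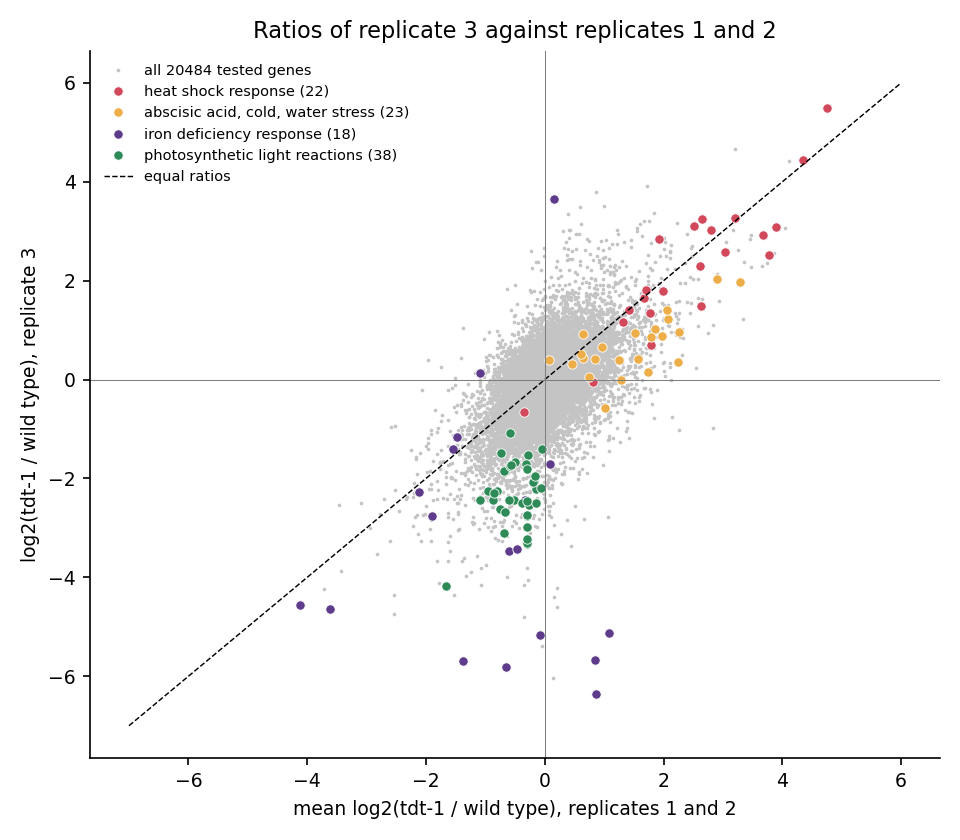
Log2 ratio of tdt-1 over wild type on replicate 3 (y axis) against the mean of replicates 1 and 2 (x axis), with a point per tested gene and 4 gene lists in colour. Heat shock genes lie near the line of equal ratios, most photosynthesis genes lie below it, and the iron list splits into genes near the line and genes far below it, such as AT1G47400 at −6.35 on replicate 3.

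In a model with genotype and dye, 9129 genes passed the test of the dye term, 5552 with Cy5 higher and 3577 with Cy3 higher. With only replicate 3 swapped, that term holds whatever set replicate 3 apart. Its SE rests on the difference between replicates 1 and 2 alone. Its smallest p values belonged to AT1G47400 (3.61, SE 0.08, adjusted p = 0.000189), BHLH38 (3.26, SE 0.07) and AT2G14247 (3.09, SE 0.07), and AT2G14247 stood at 0.01, 0.27 and −6.04 on replicates 1, 2 and 3. With the scanner's own log ratio 1736 genes passed.

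Changed genes were spread over the genome. The share of tested genes that changed lay between 12.7% on chromosome 3 and 14.1% on chromosome 5 (one-sided permutation p = 0.404). The densest window of 100 neighbouring tested genes held 28 changed genes, between AT2G40250 and AT2G41310, against a median of 26 in the densest windows of random draws (one-sided permutation p = 0.139). In windows of 50 genes the p was 0.0373. In the window of 100 the members with the smallest p were the abscisic acid receptor gene PYL6 (−1.91 ± 0.05), AT2G41190 (1.6 ± 0.19), AT2G40435 (1.05, SD 0.004) and AT2G40400 (−0.96 ± 0.08).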

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

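The test of dye bias was chosen only after the result was seen, and the bounds of the test that turns the ratios were written after it, while the tests of dim spots and saturation were chosen before. Probes that carry no locus code were left out of the gene comparison, and changes appeared among them as well. Of 3091 such probes tested in the same way with limma, 49 were higher in tdt-1 and 36 were lower. That is a smaller share than among the genes, where 1508 of 20484 were higher and 1222 lower. The probes were fitted and adjusted as a set of their own and not matched to the genes on signal. The shares therefore rest on unlike cutoffs of the unadjusted p. They comprised 1911 probes named by a chromosome position, of which 25 were higher and 15 lower, and 1180 probes for expressed sequences and others, of which 24 were higher and 21 lower. The genome build of the positions is not given in the sources used here, so no coordinates are reported.

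The 2730 changed genes were set against the other ways of turning the ratios of the 3 arrays. Each array's ratio can be taken with or without its sign turned, which gives 4 ways, the real one included, and 1 of the 4 gave as many genes. The highest count among the other ways was 0 (limma), with 7, 2 and 1214 genes at an unadjusted p under 0.05. The last belongs to the way that sets Cy5 over Cy3 on every array. With 4 ways, the design cannot give a share under 0.05.

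Replicate 3 stood apart from replicates 1 and 2 in its ratios, for example in photosynthesis genes, whose median was −2.43 there against −0.27 and −0.36. Noise of dim spots would leave bright genes in good accord, but among the 5121 brightest genes replicate 3 correlated with the mean of replicates 1 and 2 at r = 0.554 across genes, while replicates 1 and 2 correlated at 0.971 there. Dye bias of single probes without regard to function would spare gene lists, but 14 of 26 lists differed between replicate 3 and the others beyond the central 95% of 10000 random lists of like signal. Saturation of bright spots on replicates 1 and 2 could account for the photosynthesis genes only if unsaturated members differed little, yet over 23 members without a saturated spot there, replicate 3 lay lower by a median log2 difference of −1.79. An effect of array format, scan or software without regard to function would spare gene lists too. The same 14 of 26 lists therefore argue against it as the whole cause for these lists. What stays open is a difference of plants, growth or RNA between replicates, and an added part of format, scan day or software. Their shares cannot be told apart because all of them coincide with the dye orientation.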

How the results depend on the processing

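Averaging replicates 1 and 2 was chosen after seeing the data. For the values below, the cause was not tested. Of the 2730 changed genes, all kept their sign in each alternative that tested them, except 1 with the mean over probes of a locus, and none of the 11 calls of gene lists by camera turned to the opposite direction. Where arrays were left out, averaged or weighted, or a dye term was added, the sign of these genes could not turn. Each of them had the same sign on all 3 arrays to begin with. Median centring moved the median of all genes to 0.10, from 0.02, the largest such shift. Of 119 named genes, 101 no longer passed with median centring, 55 without replicate 1, 67 without replicate 2 and 79 with replicates 1 and 2 averaged, while 17 more passed with the dye term and 13 more with array weights or without replicate 3. The passes gained with the dye term, with array weights or without replicate 3 rest wholly or mainly on the spread between replicates 1 and 2. With no background correction 9 named genes no longer passed, with the trend and robust variance 5, and with the scanner log ratio 4. Signal over background limits what can be tested: 18722 loci were tested where both genotypes had to be well above background, and 25572 with no filter.

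With median centring 1 gene was higher and 0 were lower, and the 1 gene changed at least 2-fold, with 0 lower. The list medians there were 0.16 for brassinosteroid genes and 0.086 for cell wall genes, both turned, 0.34 for ribosomal proteins, which passed, and 0.21 for the cell cycle and 0.63 for seed storage, which no longer passed, and TDT turned to 0.13. With array weights (1.27, 7.40 and 0.11 for replicates 1, 2 and 3) 8170 genes were higher and 6710 lower, 717 of the former at least 2-fold. There the direction turned for brassinosteroid genes (0.00094), the circadian clock (0.36), ribosomal proteins (−0.013) and flavonoid genes (−0.25), and for TDT (0.059), AT1G47400 (0.88), BHLH38 (0.86) and AT2G14247 (0.16), while root hair markers (−0.30) and salicylate genes (0.29) passed and phosphate genes (0.17) no longer did. With a dye term 6941 genes were higher and 6260 lower, 747 of the latter at least 2-fold. With replicates 1 and 2 averaged 24 were higher and 19 lower, all 24 and 19 at least 2-fold. Both gave the same list medians: 0.090 for the cell cycle, which no longer passed, 0.20 for ribosomal proteins, which passed, and 0.16 for cytokinin genes and 0.20 for root hair markers, whose camera direction turned.

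With the scanner log ratio and with the series table alike, 944 genes were at least 2-fold higher and 691 lower, against 466 and 379. There brassinosteroid (−0.074) and cytokinin genes (0.11) turned in camera direction, the cell cycle (0.16) no longer passed and ribosomal proteins (0.16) did, and with the scanner log ratio 1736 genes passed the dye test, against 9129. Without background correction phosphate genes (−0.89) no longer passed, and with an offset of 16, 705 genes were at least 2-fold higher. With no filter on dim probes ribosomal proteins (0.10) passed, and with both channels well above background the carbon starvation list (0.23) turned in camera direction. In windows of 50 genes the permutation p of the densest window was 0.0373, in windows of 200 it was 0.344 and with the calls of the dye term fit 0.854.

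With camera at an estimated correlation, 0 lists were higher and 0 lower. The lists that no longer passed there, with their unchanged medians, were abscisic acid (1.19), auxin (−0.50), cell cycle (0.13), chlorophyll (−0.65), heat shock (2.38), iron (−1.52), oxidative stress (0.28), phosphate (−0.86), photosynthesis (−1.05), seed lipids (0.41) and seed storage (0.66). A fit with scan day as a block was not run to a result, since no correlation could be estimated from 1 array on 1 of the days. Within the day shared by replicates 1 and 2 the values are those without replicate 3, and the other day holds 1 array and no test.

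Leaving out each array in turn, the genes higher ranged from 66 to 7002 and those lower from 45 to 5463, and at least 2-fold from 66 to 726 and from 45 to 383. List medians ranged from 0.080 to 0.22 for the cell cycle, −0.017 to 0.16 for cytokinin, −0.070 to 0.21 for ribosomal proteins, −0.27 to 0.17 for root hair markers, −0.075 to −0.021 for brassinosteroid, −0.22 to 0.066 for the cell wall, 0.056 to 0.42 for the clock, −0.27 to 0.17 for flavonoids, 0.082 to 0.34 for jasmonate, −1.19 to 0.013 for phosphate and 0.15 to 0.37 for salicylate. TDT ranged from −0.34 to 0.080, AT1G47400 from −2.83 to 0.86, BHLH38 from −2.49 to 0.84 and AT2G14247 from −3.01 to 0.14.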

Other observations

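All tests in this part were chosen only after the result was seen. Since 4 genes of methionine chain elongation were among the 15 lowest, a list of the aliphatic glucosinolate pathway was drawn up after seeing the data. Of 22 tested members 15 fell, none rose and 20 were lower on all 3 arrays, at a median of −1.36, with the 4 genes that prompted the list among them. BAT5, a plastid transporter of the chain elongation, fell by 2.43 ± 0.19, CYP83A1 of the core structure by 1.76 ± 0.28, the isomerase subunit IPMI1 by 2.06 ± 0.38 and the sulfotransferase SOT18 by 1.46 ± 0.24, while IIL1, the large isomerase subunit shared with leucine synthesis, stood at −0.02 ± 0.06. A candidate reading is that lower transcript levels extend along the pathway beyond the 4 genes that prompted the list. The 18 members outside the 15 lowest had a median of −1.15, with 11 that fell, 7 that did not pass and 16 lower on all arrays (camera p = 2.58e-10, and p = 0.0424 with an estimated correlation, unadjusted). These values describe the extent of the fall, and its cause was not tested.

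Factors of mRNA decay other than DCP2 were also listed after seeing the data. Of 14 tested, 2 rose, none fell and 12 did not pass. The share that passed is near that of all tested genes, of which 2730 of 20484 passed. As a list they did not pass camera at an unadjusted threshold of 0.05. The members that rose were SOV (AT1G77680), an exoribonuclease of cytoplasmic mRNA decay (1.17 ± 0.23, adjusted p = 0.0203), and LSM1B, of the complex that promotes decapping (1.0 ± 0.35, adjusted p = 0.0355). DCP1 and VCS, partners of DCP2 in the decapping complex, stood at 0.11 ± 0.08 and 0.11 ± 0.03 and did not pass.

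Of 22 heat shock genes 20 rose, at a list median of 2.38. Heat or handling confined to the samples of 1 scan day would raise them on that day alone, but the lowest list median on any array was 2.31. A difference in handling between tdt-1 and wild-type seedlings that recurred in each replicate could give the same values and was not tested. RNA of seeds that had not germinated could raise seed transcripts along with them: 9 storage protein and oleosin genes had a median of 0.66, at 0.48, 0.12 and 1.06 on replicates 1, 2 and 3, below the heat shock list's 2.31, 2.78 and 2.41. All 9 lay among the 5121 dimmest genes, so a share of such RNA cannot be told apart from its absence. Which difference between the tdt-1 and wild-type samples accounts for the rise was not tested.

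Of 18 iron deficiency genes 6 fell, and the list, with a median of −1.52 over all arrays and −0.62 without replicate 3, was split after seeing the data. The 7 genes made up of FRU (also called FIT) and uptake genes that need it, 6 of which fell, had medians of −1.88, −1.91 and −2.26 on replicates 1, 2 and 3. Over the mean of replicates 1 and 2 their median was −1.90, beyond the SD of 1.15 between members, so their fall was not seen on replicate 3 alone. That describes these genes and is no independent test of such a difference, since 6 of them had passed the test over the 3 arrays before the split. A smaller share of root RNA could lower root genes, and root hair markers had medians of −0.22, −0.34 and 0.55, but these lay above those of the 7 genes by at least 1.57 on each array, beyond the SD between markers (0.35, 0.35 and 0.65), which argues against such a share as the whole cause of their fall. The 10 iron genes upstream of FRU or beside it, none of which passed, had medians of −0.40, −0.01 and −5.15. As a set, their large fall was seen on replicate 3 alone, where the 10 ratios ran from −1.70 for OPT3 to −6.35 for AT1G47400. Over the mean of replicates 1 and 2 their median was −0.20, within the SD of 0.79 between members. Only 5 of the 10 were lower on all 3 arrays. Whether the set also lay slightly lower on replicates 1 and 2 stays open. A root share was not decided by these values. On replicate 3, where the 10 genes fell, the root hair median lay above theirs by 5.7, so root hair markers did not share the fall on that 1 array. On replicates 1 and 2 it differed from theirs by 0.18 and −0.34, with little fall of the 10 genes there to account for.

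The iron store gene FER1 stood at 0.78, −0.47 and 3.64 on replicates 1, 2 and 3.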
